A study of Xenopus laevis with 3 samples.

How the data were processed

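Liver RNA of female African clawed frogs (Xenopus laevis) was measured on 3 Affymetrix arrays, 1 each for frogs given the solvent DMSO, pregnenolone or artemisinin. The labels state that 3 frogs were injected with each compound on 2 consecutive days, at 50 mg/kg for pregnenolone and 200 mg/kg for artemisinin, and that the control group received DMSO in parallel. They do not spell out the number of control frogs. Frogs were kept in water at 22 °C and killed 24 h after the second injection. The RNA of the frogs of a group was pooled before labelling, and biotinylated cRNA was made from 6 ug of total RNA.

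The deposited values are log2 expression values from robust multiarray averaging (RMA), which the authors ran in a version that is not stated. RMA subtracts background, makes the distributions of the arrays alike and summarises the probes of a probe set on the log2 scale. The base of the logarithm was taken from the definition of RMA and from the range of the values, since it is not written out. Making the distributions alike removes any difference in the total amount of message between groups. The values were used as deposited. For an array the number of arrays limits the precision, and no count or depth lies behind a value.

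Each probe set was joined to the gene symbol of the platform annotation. Of 32635 probe sets, 96 were controls. A single symbol was given for 15495, several for 279 and none for 16765. Symbols were updated through the Entrez gene identifier with a RefSeq gene table, which altered 2 of them. The gene table names a genome build and the array does not, so no positions are given. The suffixes .L and .S mark the copies of a gene on the long and short chromosomes of this allotetraploid species. Probes may also bind the other copy or a paralog, so the assignment of a value to 1 copy is uncertain.

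With 1 array per group there was no replicate spread, and no test between groups or p-value was computed. Differences of log2 values were taken for pregnenolone minus DMSO, artemisinin minus DMSO and artemisinin minus pregnenolone. Probe sets whose mean over the 3 arrays was at or above that of the median probe set (5.61) entered the counts, which left 16270. A probe set was counted when it differed by at least 2-fold. Each gene was represented by its probe set with the highest mean, which gave 7478 genes. Technical spread was gauged from the 1287 genes with over 1 probe set above the filter. That measure leaves out variation between frogs and between arrays.

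There were 33 gene lists, chosen before the data were examined, for drug metabolism, lipid and glucose metabolism, stress responses, secreted proteins, basic cell functions and the markers of other cell types. Members were matched by symbol or by a synonym in the gene table. A list with at least 5 measured genes was described by its median difference, with a 95% order-statistic interval over its genes, and by its place among the medians of 10000 random lists of equal size matched on mean level in 20 bins. Genes of 1 pathway are correlated, so random lists vary less than real ones, and a median outside their central 95% is a description and no test. Such medians were common. Of 32 lists, 6 lay above and 10 below the range with pregnenolone against DMSO, and 7 and 9 with artemisinin against DMSO. With artemisinin against pregnenolone 11 lay above and 6 below, so a place outside the range does not by itself set a list apart. Members were counted as different at 1.5-fold. The list of pigment cell genes had 3 measured genes and is given by values.

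The genes named were fixed by a rule before the data were examined: the 12 highest and 12 lowest genes with a proper symbol for each comparison with DMSO, the 6 highest and 6 lowest between the compounds, up to 4 members of each list with the largest difference in each comparison, and nr1i2, nr1i3, alas1, por and all measured CYP family 2 and 3 genes. No probe set in the annotation used here carries the symbol nr1i3, so that gene was not analysed here. Other list members named as examples were chosen after their values were seen.

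Both comparisons with DMSO share 1 array. Their overlap was set beside 100 simulations of unchanged arrays against 1 shared control, which treat all spread as noise, and beside the overlap of independent lists. The alternatives were other fold thresholds, other level filters, median centring, quantile normalization, removal of a loess trend on mean level (span 0.3), exclusion of probe sets marked for cross-hybridisation, 1 probe set per gene, the mean of the probe sets of a gene above the level filter and unmatched random lists. Exclusion of the markers of other cell types and of members matched only by a synonym was chosen after seeing the data. A pseudocount alternative planned for linear values did not apply to log2 values.

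The steps were tested on simulated data of 7478 genes. Of 50 genes given a log2 difference of 1.5, 98.0% were recovered, and of 100 unshifted lists 3.0% lay outside the central 95% of random lists. The simulated noise was independent between genes, with the median spread of the level for each gene. These rates check the steps and do not describe the real arrays, where spread differs between genes of a level and genes of 1 list are correlated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.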

Results

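Livers of female Xenopus laevis were profiled after injection of DMSO, pregnenolone or artemisinin to find target genes of xlCAR, the frog form of the constitutive androstane receptor, a nuclear receptor that in mammals controls drug-metabolising enzymes. Pregnenolone is a steroid made from cholesterol and the precursor of the steroid hormones. Artemisinin is an antimalarial drug. The compounds were given at different doses, 50 and 200 mg/kg. Each group is 1 array of pooled RNA, so no value below has a replicate error and none of the differences was tested. The median value was 5.62 on the DMSO array, 5.61 on the pregnenolone array and 5.62 on the artemisinin array. Across probe sets the pregnenolone array correlated with the DMSO array at r = 0.988 and the artemisinin array at r = 0.992. Probe sets are not independent replicates.

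The first comparison asked which liver genes differ after pregnenolone. The highest differences from DMSO were for sftpc.S (Entrez gene 779071), which encodes a surfactant protein, at 24.7-fold (log2 difference 4.63), for the carrier gene slc16a6.L (379999) at 19.9-fold (4.31) and for acsl4.S (100174803), which activates long-chain fatty acids, at 14.0-fold (3.80). They were followed by slc41a3.L (3.38), the lipid transporter mfsd2a.L (3.16), the cobalamin carrier tcn2.L (2.84), spats2.L (2.73), the water channel aqp3-a (2.72), the kinase pim3.L (2.68), apolipoprotein apoa1.L (2.51), the amino acid transporter slc1a5.S (2.5) and tent5a.L (2.36). Other probe sets of these genes gave smaller differences: the mean over the probe sets above the level filter was 3.19 for acsl4.S, 2.66 for mfsd2a.L and 2.29 for pim3.L, a further acsl4.S probe set below the filter differed by 1.09, and a second probe set of tent5a.L differed by 0.30. The DMSO values of sftpc.S (5.38), slc16a6.L (5.36) and spats2.L (4.66) lay below the level filter, and no detection calls were used here, so these differences depend on the background. In all, 272 probe sets were at least 2-fold higher and 246 at least 2-fold lower, out of 16270. Of the 24 most different probe sets, 11 had no usable symbol.

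Among the 12 genes furthest below DMSO were 6 digestive enzyme genes of the exocrine pancreas, with a median difference of -4.55, and copies of glucose-6-phosphatase, the last enzyme of glucose release. The gene prss3.S (447093) stood at 11.39 on the DMSO array and 4.56 on the pregnenolone array, a difference of -6.84. The others were ctrb1.L (-5.28), cela3a.S (-4.82), ctrc.L (-4.27), cela3b.L (-4.01) and prss1.L (-3.88). They were as low on the artemisinin array, so they set the DMSO array apart from both treated arrays. The pancreas and gut list, with 10 measured genes, had a median of -3.95. It includes prtn3.L, a leukocyte protease matched through a synonym. The glucose-6-phosphatase copies were g6pc1.2.S (-3.89), g6pc1.1.L (-3.60), g6pc1.1.S (-2.92) and g6pc1.3.L (-2.88). Also among the 12 lowest were darmin.L (-3.50) and nat16.S (-3.17). The pregnenolone values of prss3.S, ctrb1.L (5.47), cela3a.S (5.55), darmin.L (4.14) and nat16.S (4.70) lay below the level filter, so the size of these differences depends on the background. Second probe sets of ctrb1.L and darmin.L, at levels of 3.16 and 3.78, did not differ.

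Genes of cholesterol synthesis and uptake were higher with pregnenolone. Of 22 measured, 13 were at least 1.5-fold higher and 0 lower, with a median of 0.705 (95% interval over genes 0.11 to 1.0) that lay above the central 95% of random lists. They included acat2.L (1.93), hmgcs1.L (1.92), ebp.L (1.48) and hmgcs1.S (1.3). Fatty acid and triglyceride synthesis had 11 of 34 genes higher and 1 lower, with a median of 0.24 (-0.03 to 0.6) above the random range. Besides acsl4.S its members included fads2.S (1.12), elovl1.L (1.12) and fads2.L (0.95). The oestrogen response and yolk precursor list had a median of 0.25 (-0.11 to 0.55), above the random range, with esr1.L, the oestrogen receptor, at 0.73. Within it the yolk protein genes vtga2.L and vtgb1.L differed by 0.02 and 0.03, at levels near the top of the scale (14.37 and 14.51 on the DMSO array). Bile acid synthesis had a median of -0.21 (-0.67 to 0.13) below the random range, with slc27a2.L at -1.26. Its member scp2.L was at 0.61, and a second probe set of that gene was at -0.83.

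Lists of glucose handling, complement and secreted proteins had medians below the random range. Of 39 genes of gluconeogenesis and glucose handling, 16 were at least 1.5-fold lower and 0 higher, with a median of -0.41 (95% interval -0.70 to -0.16) below the random range. Another glucose-6-phosphatase copy, g6pc1.2.L, was at -2.24. Members of this list matched by synonym, such as irs4.L (-0.63) and khsrp.S (-0.18), do not act in gluconeogenesis. Acute phase and complement genes had 12 of 42 lower and 2 higher, with a median of -0.41 (-0.57 to -0.22) below the random range, among them cfb.S (-1.34), c6.1.L (-1.25), c1r.L (-1.11) and c1s.L (-1.01). Of 41 genes of secreted hepatocyte proteins and coagulation, 13 were lower and 2 higher, with a median of -0.22 below the random range. The list included the transthyretin gene ttr.L (-1.86), kng1.L (-1.64) and serpinc1.L (-1.10), while apoa1.L was higher. The apoe.L probe set used was at -1.21 and another probe set of the gene at 0.28. Among 45 genes of the urea cycle and amino acid breakdown, 14 were lower and 2 higher, such as aldh4a1.L (-1.48), tdo2.L (-1.28) and amt.L (-1.26) against glul.L (1.5), yet the median of -0.04 lay within the random range (below that of lists not matched on level).

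Drug-metabolism genes differed in both directions with pregnenolone. Of 20 genes of CYP families 1 to 4, 3 were at least 1.5-fold higher and 5 lower, with a median of -0.12 (95% interval -0.40 to 0.43) below the random range. The gene cyp2a6.1.S (379297) was 3.24-fold higher (1.70), cyp2f1.S (398935) 1.79-fold higher (0.84) and cyp3a4.2.L (100037189) 0.63 higher. Lower were cyp4f2.L (-1.96), cyp2a6.3.L (-1.34), cyp2a6.1.L (-0.95) and cyp2a6.9.L (-0.94). Small differences were seen for cyp2c8.2.L (0.43), cyp3a4.1.L (0.30), cyp2c8.1.L (0.01), cyp3a5.L (-0.06), cyp2a6.10.L (-0.29) and cyp2b6.L (-0.29), and cyp2d6.S did not differ (10.12 on both arrays). Other phase I enzymes had a median of -0.19 (-0.37 to 0.05) below the random range, with adh1b.L at -1.68, dpyd.L at -1.3 and fmo5.2.S at -1.01. The medians of the glutathione and UDP conjugation list (0.00), the other phase II transferases (0.02), the transporters of drugs and bile acids (0.01), the nuclear receptors (0.00), heme synthesis (0.01) and iron handling (0.03) lay within the random range. The gene nr1i2.S (399017), whose symbol in mammals stands for the pregnane X receptor, was at 6.40 with DMSO and 7.63 with pregnenolone. The difference was 1.23, and 0.44 at the second probe set of the gene. Of the genes for 5-aminolevulinate synthase, which starts heme synthesis, alas1.L (398824) was 1.24 higher and alas1.S (444480) 0.69 higher. P450 oxidoreductase, por.L (379707), differed by 0.24.

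In the remaining lists the unfolded protein response and ER chaperones had a median of 0.24 above the random range, with 11 of 61 genes higher and 7 lower, including ssr4.L (1.49), dnajb9.L (1.40), hspa5.S (1.22) and xbp1.L (0.84). Oxidative phosphorylation (0.18, 92 genes) and the proteasome (0.18, 61 genes) lay above the random range with small differences, the largest being ndufaf4.L (0.82) and psmd14.L (0.81). Cell cycle and DNA replication had a median of -0.19 below the range. Without the level filter this median was -0.10. Its extremes were birc5l.S (-1.68), with a second probe set at -0.50, and cdk2.S (1.12). Cytosolic heat shock (-0.02), oxidative stress and NRF2 targets (0.00), fatty acid oxidation (-0.01), steroid hormone metabolism (0.04), cell death and p53 response (0.00) and cytosolic ribosomal proteins (0.02) lay within it. Beside these groups, markers of other cell types also differed: leukocyte genes had a median of -0.21 and the list of biliary, stellate, endothelial and fibroblast genes -0.22, both below the random range, with acta2.L at -1.82 and tagln.S at -1.79. The erythrocyte list (0.03), muscle list (-0.02) and oocyte and ovary list (0.00) lay within it. The 3 pigment cell genes were pnp.L (1.08), slc45a2.L (-0.07) and rab27a.S (-0.62). Without the markers of other cell types, 271 probe sets were higher and 233 lower. For 42 genes whose first probe set differed by at least 2-fold, the second had the same sign in 40 and also passed 2-fold in 19. The SD between probe sets of 1 gene was 0.240.

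The second comparison asked the same of artemisinin. The highest gene was akr1c2.L (379255), an aldo-keto reductase, at 31.2-fold over DMSO (log2 difference 4.96). The heat shock gene hsp70.L (398343) was 19.5-fold higher (4.29), the prostaglandin synthase gene ptgs2.S (446781) 14.7-fold (3.88), the chemokine gene cxcl8.L (100036815) 14.0-fold (3.81) and pck1.L (379844), a key enzyme of gluconeogenesis, 10.1-fold (3.34). A second ptgs2.S probe set differed by 1.89. The DMSO values of hsp70.L (5.63), cxcl8.L (5.72), ptgs2.S (5.44) and pck1.L (5.32) lay near or below the level filter, so these folds depend on the background. The other genes among the 12 highest were olfm4.L (3.26), glutathione transferase gstp1.L (3.12), zfand2a.L (2.87), slc1a5.S (2.62), pir.L (2.48), cyp2f1.S (2.44) and higd1a.L (2.40). In all, 201 probe sets were at least 2-fold higher and 101 at least 2-fold lower. Of the 24 most different, 4 had no usable symbol.

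The lowest genes were the 6 digestive enzyme genes, from prss3.S (-6.92), ctrb1.L (-5.28) and cela3a.S (-5.01) to ctrc.L (-4.62), prss1.L (-4.12) and cela3b.L (-4.0), with a median of -4.81. The artemisinin values of prss3.S (4.47), ctrb1.L (5.47), cela3a.S (5.37) and ctrc.L (5.35) lay below the level filter, so the size of these differences depends on the background. The pancreas and gut list had a median of -4.06, although pnliprp2.L was 1.2 higher. They were followed by g6pc1.3.L (-2.63), the smooth muscle actin gene acta2.L (-2.27), g6pc1.1.L (-2.14), itln2.L (-2.12), the carbonic anhydrase gene ca2.S (-1.97) and g6pc1.1.S (-1.94).

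Among drug-metabolism genes, cyp2f1.S was 5.43-fold higher with artemisinin, from 8.12 to 10.56, and cyp1a1.S was 1.06 higher. Of the 20 CYP genes, 17 lay within 1.5-fold of DMSO with a list median of -0.04 inside the random range. The lowest was cyp2a6.3.L at -0.99. Nearer to DMSO were cyp2c8.2.L at -0.38, cyp2b6.L at -0.13, cyp2a6.9.L at -0.08, cyp2a6.1.S at -0.07, cyp3a5.L at -0.07, cyp2a6.1.L at -0.05 and cyp2c8.1.L at -0.05. Slightly above DMSO were cyp3a4.1.L (0.07), cyp2a6.10.L (0.14), cyp2d6.S (0.26) and cyp3a4.2.L (0.29). Of the heme synthesis genes, alas1.S was 5.05-fold higher (2.34) and alas1.L 4.01-fold higher (2.0), while alad.S was at -0.80 and the list median of -0.05 lay within the random range. The difference was 0.50 for nr1i2.S, with -0.04 at its second probe set, and 0.06 for por.L. The nuclear receptor list had a median of 0.08 above the range, with 34 of 36 genes within 1.5-fold. Its largest members were rxrg.L (-0.84) and cyp1a1.S, which is a target gene matched through a synonym and no receptor. Other phase I enzymes had a median of -0.10 (-0.17 to 0.06) just below the range, with akr1c2.L and aldh1a1.L (1.14) higher. The transporter list had a median of 0.10 (-0.29 to 0.2) at the upper edge of the range, with slc22a4.L at 0.88 and slco2b1.L at -0.87. Other phase II transferases (-0.01) and iron handling (0.01) lay within it.

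Part of the heat shock and antioxidant lists was higher with artemisinin. Of 29 cytosolic heat shock genes 7 were at least 1.5-fold higher and 0 lower, with a median of 0.32 (95% interval 0.14 to 0.53) above the random range, including hspa8.L (1.65), ahsa1.L (1.55), dnaja4.1.L (1.54) and hspa1a.S (1.35). Of 45 oxidative stress genes and targets of NRF2, the regulator of antioxidant genes, 10 were higher and 2 lower, with a median of 0.09 (-0.02 to 0.46) above the range. The glutathione synthesis gene gclm.L (2.07), gsr.L (1.36), sqstm1.L (1.34) and txn.L (1.09) were higher, and prdx2.L (-1.25) and cat.1.L (-1.04) lower. Both lower genes had also been put on a second list of erythroid genes, and the erythrocyte list was lower on this array too (median -0.45). Whether these 2 genes follow the blood in the pool was not tested. Glutathione and UDP conjugation had 5 of 19 genes higher and 0 lower, with a median of 0.12 (-0.23 to 1.01) above the range, among them gclc.S (1.22). The 4 other probe sets of gstp1.L were higher too, and the mean of all was 3.5. The proteasome list had a median of 0.22 above the range, with 59 of 61 genes within 1.5-fold. Its lowest member psmd3.S was at -1.09, or -0.26 as the mean of its probe sets. Acute phase and complement genes had a median of 0.03 (-0.03 to 0.18) above the range. Of the 42 genes 8 were higher and 4 lower, the higher ones including socs3.S (1.35) and junb.L (1.21) beside cxcl8.L. The lower bpi.4.S (-0.92) was matched through a synonym. Unfolded protein response genes had a median of -0.05 within the range (below that of lists not matched on level), with hspa5.S at 1.22 and atf3.L at 1.16.

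Gluconeogenesis and glucose handling had a median of -0.16 (-0.27 to -0.09) below the random range, with 5 of 39 genes lower and 3 higher. Its members diverged, with pck1.L and tat.S (1.40) above DMSO and the glucose-6-phosphatase copies below. Urea cycle and amino acid breakdown (-0.15), bile acid synthesis (-0.16) and steroid hormone metabolism (-0.12) also had medians below the range, although akr1d1.S, a member of the last 2, was 1.17 higher. The medians of cholesterol synthesis (-0.01), fatty acid and triglyceride synthesis (0.01), fatty acid oxidation (-0.04), the oestrogen response list (0.01), secreted hepatocyte proteins (-0.05), cell cycle (0.00), cell death (0.03), oxidative phosphorylation (-0.06) and ribosomal proteins (-0.01) lay within it. That of oxidative phosphorylation lay below the range of lists not matched on level.

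Markers of other cell types differed beside these groups. Of 22 erythrocyte genes 8 were at least 1.5-fold lower with artemisinin and 0 higher, with a median of -0.45 (-0.75 to -0.15) below the random range. They included hbz.L (-1.68), hba3.L (-1.44), alas2.S (-1.08) and alas2.L (-0.75). The globin genes hbg1.L and hba1.S differed by -0.03 and -0.05 at levels of 14.56 and 13.99 on the DMSO array, whose maximum was 14.59. The list of biliary, stellate, endothelial and fibroblast genes had a median of -0.34 below the range, with tagln.L at -1.80, tagln.S at -1.76 and sox9.S at -1.09, against timp-1.L (1.80) and cldn5.L (1.31). The leukocyte list had a median of -0.12 (-0.25 to 0.02) below the range. Muscle (0.01) and oocyte and ovary genes (0.08) lay within it, with des.1.L of the muscle list at -1.32. The pigment cell genes rab27a.S, pnp.L and slc45a2.L were at -0.49, -0.18 and 0.00. Without the markers of other cell types, 198 probe sets were higher and 84 lower. For 20 genes whose first probe set differed by at least 2-fold, the second had the same sign in 15 and also passed 2-fold in 9.

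**Figure D1:**
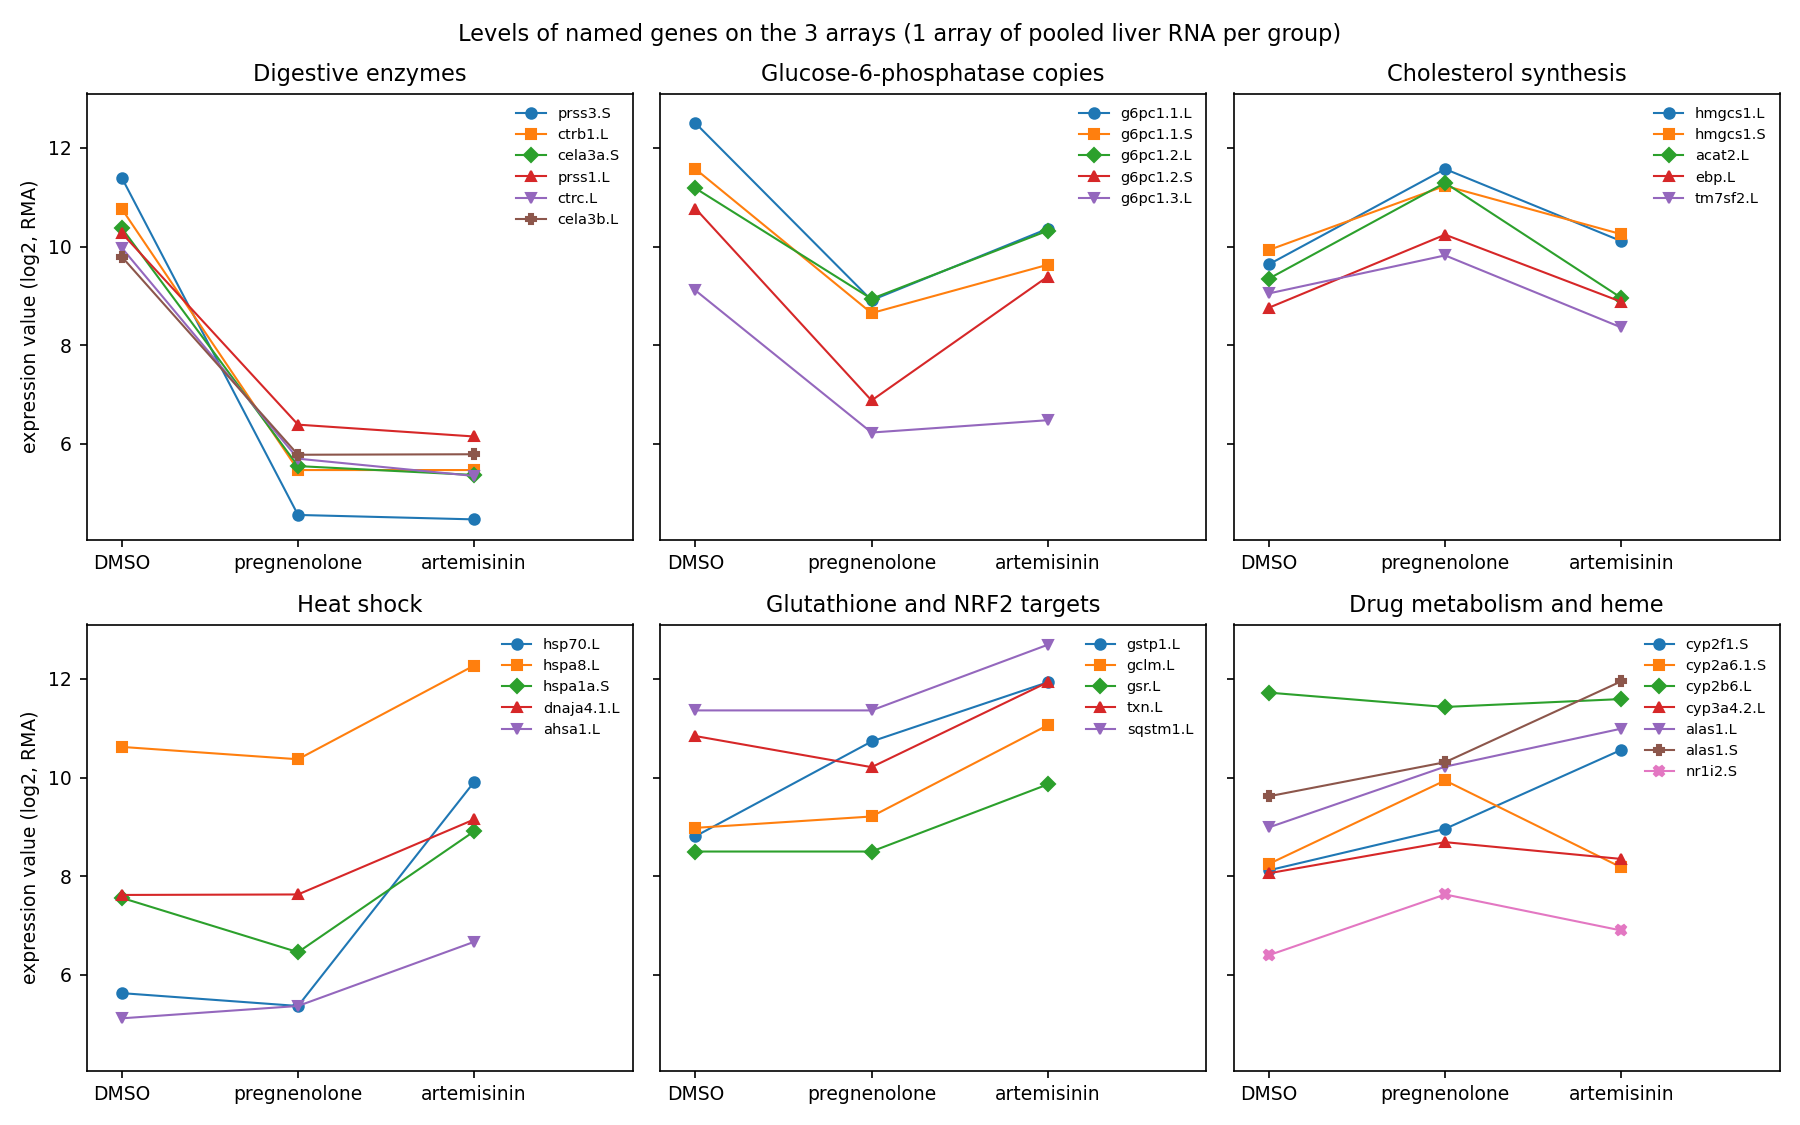
Log2 expression values (vertical axis) of named genes on the DMSO, pregnenolone and artemisinin arrays (horizontal axis), with 1 point per gene and array and lines joining the points of a gene. The digestive enzyme gene prss3.S stands at 11.39, 4.56 and 4.47, hmgcs1.L is highest with pregnenolone at 11.57, and hsp70.L is highest with artemisinin at 9.91.

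The third comparison set the treated arrays against each other, which leaves the DMSO array out. Because the doses differ, it does not compare the compounds at matched exposure. Higher with artemisinin were hsp70.L by 23.4-fold (4.55), the interferon-induced gene mx1.L (100861583) by 17.0-fold (4.09), pck1.L by 12.9-fold (3.68), zfand2a.L (3.66), akr1c2.L (3.29) and cxcl8.L (3.23). The mx1.L value was 7.40 with DMSO, 5.26 with pregnenolone and 9.35 with artemisinin. Lower with artemisinin were sftpc.S (-4.65), slc41a3.L (-3.73), aqp3-a (-3.31), acsl4.S (-3.27), slc16a6.L (-2.74) and mfsd2a.L (-2.65). The pregnenolone values of mx1.L, hsp70.L (5.37) and pck1.L (4.97) and the artemisinin value of sftpc.S (5.35) lay below the level filter, so these differences depend on the background. In all, 334 probe sets were at least 2-fold higher with artemisinin and 225 at least 2-fold lower.

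Between the compounds the cholesterol synthesis median was -0.89 (95% interval -1.16 to -0.38), with 13 of 22 genes at least 1.5-fold lower with artemisinin and 0 higher, among them acat2.L (-2.33). The medians of oxidative phosphorylation (-0.26), the unfolded protein response (-0.20), heme synthesis (-0.29), erythrocyte genes (-0.51) and the stellate and endothelial list (-0.14) also lay below the random range. The 95% interval over genes of the heme list was -0.47 to 0.52. Its median was 0.51 with a level filter at the 75th percentile, and alas1.S was 1.65 higher with artemisinin. Above the range were acute phase and complement (0.44, with 16 of 42 genes higher and 0 lower), oxidative stress (0.35), glutathione and UDP conjugation (0.32), CYP families 1 to 4 (0.30), cytosolic heat shock (0.28), secreted hepatocyte proteins (0.28), gluconeogenesis (0.27), other phase I enzymes (0.21), cell cycle (0.16), leukocyte genes (0.12) and urea cycle and amino acid breakdown (0.11). The intervals of the CYP list (-0.05 to 0.58) and of the urea cycle list (-0.05 to 0.43) included 0. Among the CYP genes cyp4f2.L was 1.93 and cyp2f1.S 1.60 higher with artemisinin, and cyp2a6.1.S was at -1.76. The apoe.L probe set used was 1.18 higher, while the mean of the probe sets of this gene was at -0.15. The 6 digestive enzyme genes had a median of -0.13 between the treated arrays.

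**Figure D2:**
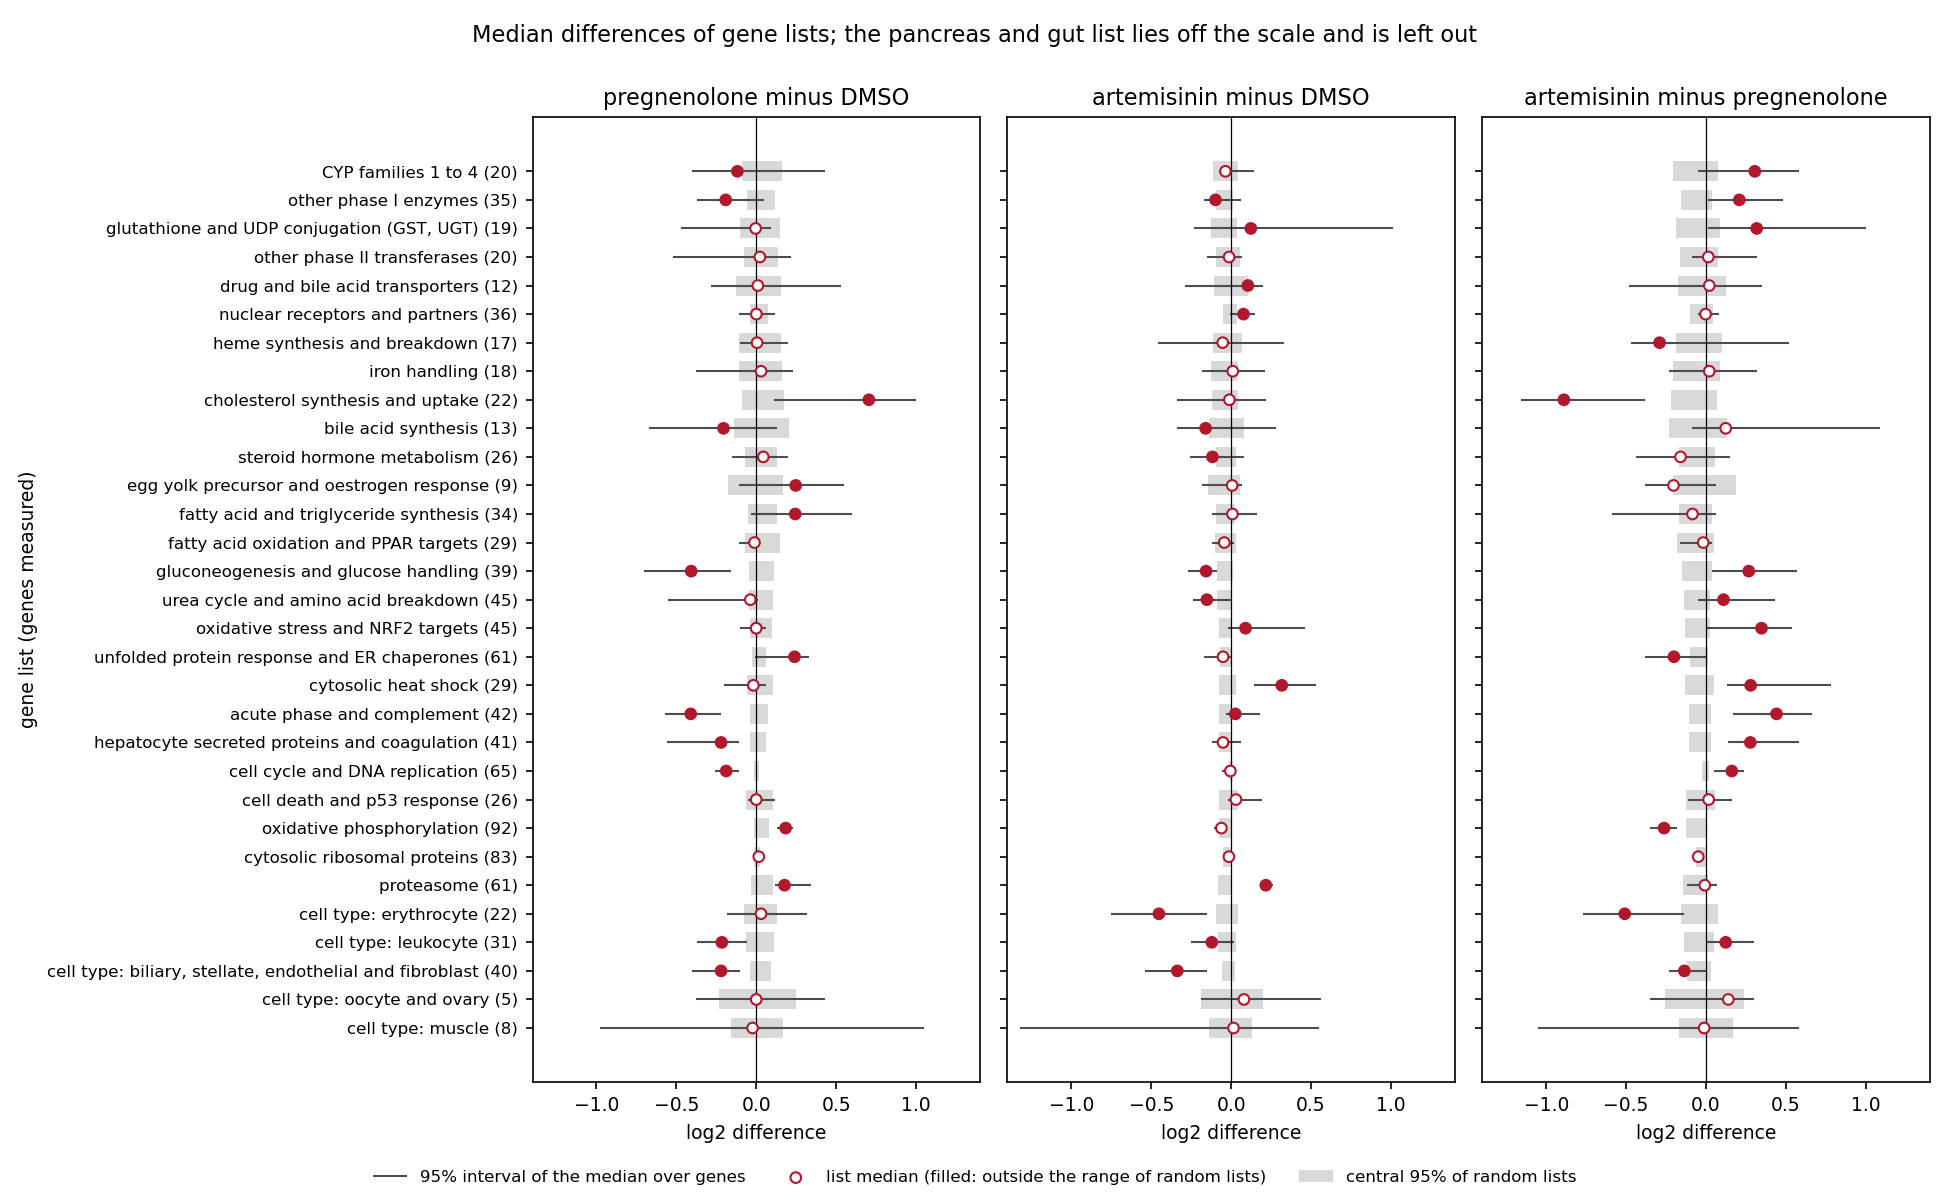
Median log2 difference (horizontal axis) of the gene lists with at least 5 measured genes, except the pancreas and gut list, which lies off the scale (vertical axis, with the number of genes measured), in the 3 comparisons. Grey bars span the central 95% of random lists matched on level, lines the 95% interval of the median over genes, and filled points lie outside the grey bar; cholesterol synthesis stands at 0.705 for pregnenolone and -0.01 for artemisinin against DMSO.

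The last comparison asked which differences the compounds shared. At least 2-fold higher with both were 49 probe sets and lower with both 32, while 0 were higher with pregnenolone and lower with artemisinin and 18 the reverse. The genes higher with both numbered 23 and included alas1.L (1.24 and 2.0), akr1c2.L (1.68 and 4.96), gstp1.L (1.92 and 3.12), slc1a5.S (2.5 and 2.62), pim3.L (2.68 and 2.29), tcn2.L (2.84 and 1.98), hspa5.S (1.22 and 1.22) and slc16a6.L (4.31 and 1.57). The 18 genes lower with both included the 6 digestive enzyme genes, g6pc1.1.L, g6pc1.1.S, g6pc1.2.S, g6pc1.3.L, acta2.L, tagln.L, tagln.S and sox9.S. Of the CYP family 1 to 4 genes none was 2-fold higher with both. The differences correlated across probe sets at r = 0.386 with a covariance of 0.0578. Unchanged arrays simulated against 1 shared control gave 87.0 probe sets higher with both, 87.5 lower with both, 10 (range 2 to 21) higher with pregnenolone and lower with artemisinin and 10.6 (4 to 19) the reverse, r = 0.499 and a covariance of 0.0830, and independent lists would share 3.36 and 1.53. The simulation counts all spread as noise, and its lists held 235 higher and 236 lower probe sets for the first compound and 235 and 234 for the second. The observed lists held 272 and 246 with pregnenolone and 201 and 101 with artemisinin, so the overlaps are not of lists of equal length. The observed values nevertheless lay below the simulated ranges: 71 to 105 for higher with both and 65 to 112 for lower with both. The ranges were 0.397 to 0.580 for r and 0.0639 to 0.109 for the covariance. The overlap is therefore no evidence of a response shared beyond the common array. With 1 DMSO array the control could not be split, so part or all of the overlap may come from that array.

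**Figure D3:**
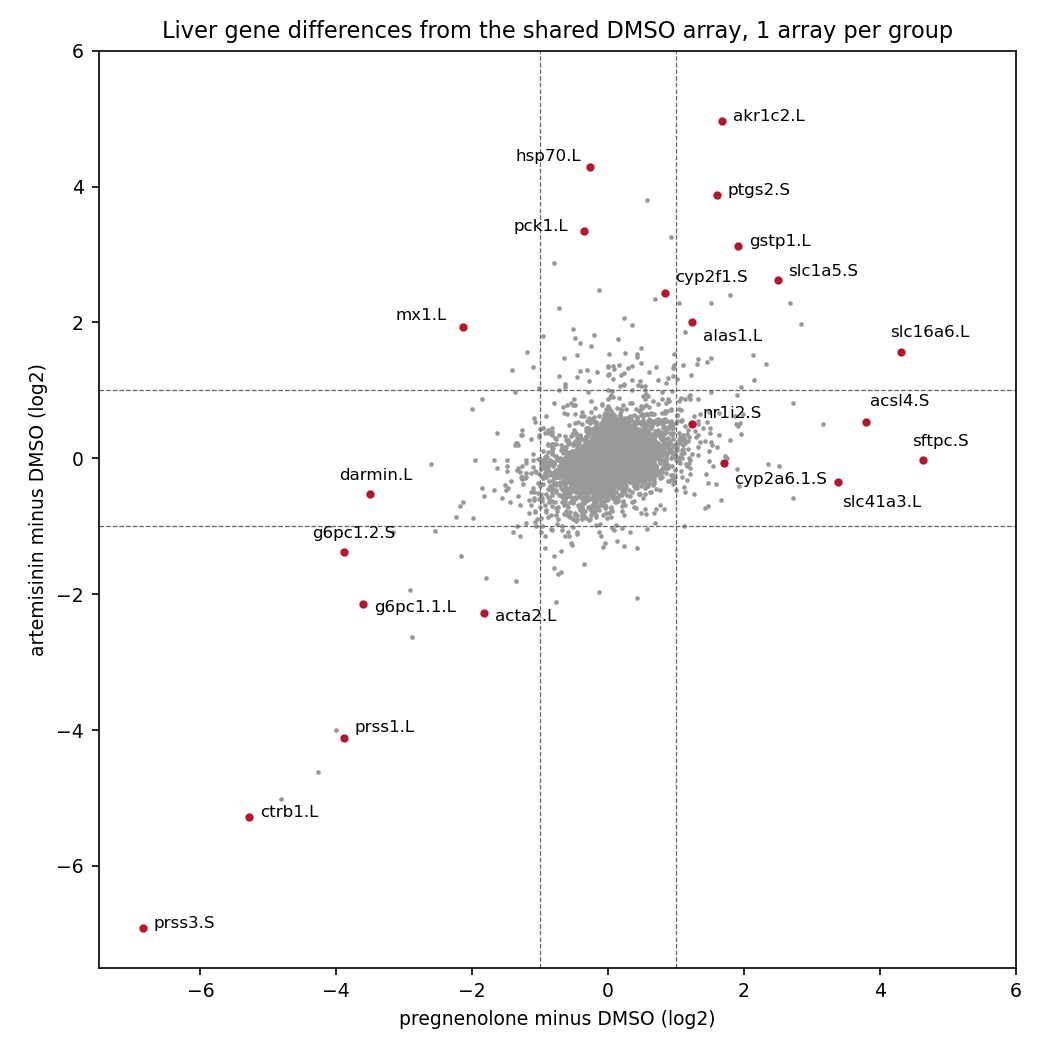
Log2 difference from DMSO of each gene with pregnenolone (horizontal axis) and artemisinin (vertical axis), with 1 point per gene, selected genes in red and dashed lines at 2-fold. The digestive enzyme genes lie at the lower left down to -6.84 and -6.92 for prss3.S, sftpc.S at the right at 4.63 and -0.03, and akr1c2.L at the top at 1.68 and 4.96.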

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

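The tests on second gene lists had bounds fixed before their values were seen, and the tests on normalization and on effects of the compounds were chosen afterwards. Genes of the second lists that also belong to one of the 33 first lists were removed only after a first result, because their values had been seen. This took the erythroid median from -0.202 over 21 genes to -0.062 over 15, and the bounds were not altered. The first value met the bound for less blood (-0.2) and the second lay between the bounds, so the removal altered the outcome.

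Hybridisation control probe sets, which detect transcripts added to the labelled sample and not used in any comparison, were higher than on the DMSO array in all 27 probe sets, by a median of 0.155 on the pregnenolone array (range 0.09 to 0.253) and 0.269 on the artemisinin array (0.116 to 0.399).

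The 6 digestive enzyme genes had a median of 10.32 on the DMSO array, 5.62 with pregnenolone and 5.42 with artemisinin. Normalization is argued against: the hybridisation controls, whose DMSO levels of 8.30 to 14.19 span those of the 6 genes, were higher and not lower on the treated arrays, by medians of 0.155 and 0.269. Pancreas tissue in the DMSO pool is a candidate explanation that stays open: 19 other acinar genes were a median of 0.203 higher on that array, between the bound for it (0.5) and the bound against it (0.1), but 13 of the 19 lay below the level filter on that array, so this median does not decide. The most different were cela1.2.L (4.68), amy2a.L (3.73), cpa1.S (2.74) and cpa1.L (2.30), while cel.2.L, cela2a.L and ptf1a did not differ at low levels of 4.71, 4.89 and 4.95. That both compounds lowered these genes in liver cannot be told apart from it, since the treated arrays differed by a median of -0.134 and there is no second DMSO pool.

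The erythrocyte genes were lower on the artemisinin array, with a median of -0.452 against DMSO. Normalization was not settled for the 11 of the 22 genes at the levels of the hybridisation controls. Their median was -0.502, while all 27 controls were higher on that array, by 0.116 to 0.399 with a median of 0.269. The controls thus went the other way, but the gap was less than the allowance of 1, a bound chosen afterwards. Normalization also stays open for the other 11 (median -0.291), which no control covers. The 22 genes lay below random lists matched on level (-0.092 to 0.044), but after RMA this cannot show a shift shared by all genes of a level. Less blood in the artemisinin pool stays open, and the outcome depended on the removal of genes already seen. The 21 other erythroid genes first tested had a median of -0.202, which met the bound of -0.2. The 15 that were left had a median of -0.062 (95% interval -0.70 to 0.00), between the bounds of -0.2 and -0.05. Among them epor.L (-0.97), gfi1b.L (-0.81) and lmo2.S (-0.80) were lower and slc2a1.L (0.79) higher. Against pregnenolone, a comparison for which no bound was set, the 15 genes had a median of -0.263 (95% interval -0.83 to -0.02), with 12 below 0 and 2 above. A lowering of erythroid transcripts by artemisinin cannot be told apart from less blood without a measure of blood in the pools.

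The smooth muscle genes acta2.L, tagln.L, tagln.S and des.1.L were lower on both treated arrays. Normalization is argued against for acta2.L and tagln.L, which lie at the levels of the hybridisation controls: their medians were -1.59 with pregnenolone and -2.04 with artemisinin, against 0.155 and 0.269 for the controls. It stays open for tagln.S and des.1.L, which lie below those levels: removing a loess trend on level moved both by less than the SD between probe sets of 1 gene (0.240), but RMA had already given the arrays nearly equal distributions, so this does not decide. More smooth muscle tissue in the DMSO pool stays open: over 17 other smooth muscle genes the medians were -0.105 with pregnenolone and -0.247 with artemisinin, and the bounds for the higher of them were -0.2 and -0.05. No test in the design separates this from an effect of both compounds.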

How the results depend on the processing

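Counts are given in the order pregnenolone higher and lower, artemisinin higher and lower (both against DMSO), and artemisinin against pregnenolone higher and lower. At 1.5-fold they were 892, 801, 477, 450, 835 and 919, at 3-fold 83, 86, 63, 26, 135 and 57, with a level filter at the 75th percentile 171, 149, 118, 52, 192 and 149, and with 1 probe set per gene 139, 104, 95, 53, 140 and 119. These settings admit more or fewer probe sets by construction. Probe sets lower with both compounds numbered 50 without a level filter, which admits more probe sets, and at 1.5-fold 153 were higher and 167 lower with both. The other 47 values of counts, overlap and agreement stayed within 1.5 times. They include those under 3 other normalizations, which moved the median difference by at most 0.012. They also include those without the markers of other cell types, a setting chosen after seeing the data. That setting drops only listed marker genes with a symbol, so it does not show how far other tissue in a pool altered the counts. Of the list medians, 688 values stayed within the interval of the main median and 8 left it or turned. Of medians outside the random range 1 turned sign, that of heme synthesis between the compounds, which was 0.507 with the filter at the 75th percentile. Of medians inside the range that left their interval, the 3 of ribosomal proteins turned sign without the loess trend and that of the cell cycle with artemisinin with the filter at the 75th percentile (0.033). Of the differences of named genes, 2345 values moved by no more than the SD between probe sets and 31 by more. None of the 792 values under quantile normalization or of the 792 without the loess trend moved by more. RMA had already given the arrays nearly equal distributions, so other normalizations could alter little, here as in the counts and list medians. All 31 came from the mean of the probe sets of a gene, a setting that cannot alter genes with 1 probe set above the filter. Of differences of at least 2-fold 1 turned sign, that of apoe.L between the compounds, to -0.15 as the mean of its probe sets. Of smaller differences that moved by more than the SD, those of scp2.L and f12.L turned sign in the same way, scp2.L with pregnenolone to -0.11. The cause of these changes was not tested. Of 96 list percentiles against unmatched random lists, 91 kept their side of the central range. The other 5 moved outside it: urea cycle with pregnenolone (percentile 2.12), unfolded protein response (1.01) and oxidative phosphorylation (0.08) with artemisinin, and bile acid synthesis (97.6) and steroid metabolism (0.94) between the compounds. Exactly the same value, to all digits given, was found on 2 or 3 arrays for 49.3% of probe sets and for 28.8% above the level filter, for a reason that was not tested. Without detection calls, how far background limits the low values is unknown.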

Other observations

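In 14 genes of the interferon response that are on none of the 33 lists, the median was lower with pregnenolone and higher with artemisinin than with DMSO. The pattern was noticed from mx1.L, which is 1 of the 6 genes highest with artemisinin against pregnenolone. Over the 14 genes, which leave out mx1.L, it was -0.433 for pregnenolone against DMSO, with 13 genes below 0, and 0.698 for artemisinin against DMSO, with 9 above 0. Examples are irf1.L, a transcription factor of the response, at 9.74 with DMSO, 9.02 with pregnenolone and 10.75 with artemisinin, the RNA sensor gene dhx58.L at 6.58, 6.13 and 8.10, eif2ak2.L at 7.04, 5.95 and 7.64, and nmi.L at 7.93, 7.14 and 8.75. Not all followed, as irf2.L was at 6.42, 5.74 and 5.36 and irf8.L at 7.23, 6.50 and 6.34.

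A hypothesis is that the interferon response as a group may lie lower with pregnenolone than with artemisinin. The list of genes and a bound of 0.3 for the median were fixed before the values of its genes were seen, except that of psmb9.S, which was left out afterwards. The median artemisinin minus pregnenolone difference was 0.806 over the 14 genes and 0.873 over 15 with psmb9.S, above the bound and above the central 95% of random lists. The 95% interval over genes was -0.01 to 1.70, with 11 genes above 0. The arrays were the ones on which the pattern was noticed, and 1 pool per group does not separate the compound from the frogs of the pool. Whether the difference comes from leukocytes was not tested. The leukocyte list differed between the compounds by a median of 0.123. Against DMSO its medians were -0.215 with pregnenolone and -0.121 with artemisinin.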
